A study of Mus musculus with 14 samples.

How the data were processed

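Polyadenylated RNA was measured in 14 libraries of bladder urothelium from mouse embryos at embryonic day 15.5. Per the labels' protocols, the urothelium was separated from the stroma after trypsin treatment, tissue of several embryos was pooled into each lysate, and mRNA was captured on oligo-dT beads and primed with random hexamers. The samples fell into 3 groups by their titles: Cre-negative littermates (n = 7), Cre-positive controls (n = 2) and Dnmt1cKO (n = 5). The controls carried the Shhcre allele and 1 floxed Dnmt1 allele, and the Dnmt1cKO embryos carried Shhcre and floxed Dnmt1 on both alleles.

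The authors deposited 1 table of RSEM expected counts for 20308 gene symbols in the 14 libraries, with no scaling to library size. The submitters' processing notes name bcl2fastq 2.17.1.14, Bowtie 0.12.9, RSEM 1.2.3 and the mm10 genome build. The gene annotation and the use of strand in counting were not given in the sources used here. Between 7.31% and 21.9% of the values of a library were not whole, and expected counts were rounded to whole numbers before testing. Totals ran from 2520509 to 13131921 counts per library. No mitochondrially encoded gene was listed. The libraries were made with PCR and no molecular identifiers are described, so intervals and floors cover counting error only. A floor of 3 counts corresponded to 0.228 CPM (counts per 1000000 of the library, here without TMM scaling) in the deepest library and 1.19 CPM in the shallowest. The p-values measure the spread between pooled lysates.

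Genes were filtered with filterByExpr, leaving 13011, and scaled by TMM. The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 with the 14 libraries of the 3 groups in 1 fit and no covariate. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. The comparisons were Dnmt1cKO against Cre-negative, Dnmt1cKO against Cre-positive control, and Cre-positive control against Cre-negative. CPM values use TMM-scaled library sizes, and errors beside them are standard deviations. Errors beside log2 fold changes are standard errors. A fold against a group with 0 counts was computed against 3 counts over that group's summed libraries and is given as a lower bound. With 1 to 3 counts the ratio has an exact 95% counting interval. Measures of whole libraries were compared by exact permutation tests, two-sided in each case and adjusted over the family of library tests.

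The gene lists, the rule for named genes and the main tests were fixed before the data were examined. The 23 lists were p53 target genes, DNA damage signalling and repair, cell cycle, germline genes silenced by DNA methylation, the X-linked Rhox and Xlr clusters, imprinted genes and clustered beta protocadherins. Others were interferon response, DNA methylation machinery, basal urothelial markers, intermediate and superficial urothelial markers, Wolffian duct markers, urogenital sinus and prostate bud markers and the Hedgehog pathway. The rest were stroma and smooth muscle, mesothelium, endothelium, immune cell, neural and glial, and erythroid markers, immediate early and heat shock genes, ribosomal protein genes, and Y-linked genes. They held 338 distinct measured genes, of which Shh, Ret and Btg2 stood in more than 1 list. Each list was tested with camera of limma 3.58.1 at an inter-gene correlation of 0.01, and again with the correlation estimated from the data. Members were counted with the p adjusted over all genes tested and adjusted over the list alone.

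Genes were named by these parts of the rule. Dnmt1, Trp53 and Shh were always named. The 8 largest rises and 8 largest falls against Cre-negative were taken among genes called in both Dnmt1cKO comparisons with the same sign, a mean of at least 5 CPM in the higher group, and the 5 Dnmt1cKO libraries all on 1 side of the other 9. Of 20 eligible higher genes 8 were named, and 0 lower genes were eligible. The wording also allows a call against Cre-negative alone with the same sign in both, under which 53 higher and 11 lower genes are eligible and 4 of the 8 largest rises are the same; those it adds are given with the other observations. Up to 4 members of each list with the smallest p against Cre-negative were named, and for the control comparison the up to 5 genes with the smallest adjusted p in each direction. Symbols of uncharacterised loci were counted and not named under the rule. The rule gave 96 distinct genes.

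Gene positions came from GENCODE M21 on GRCm38, which is the mm10 build. Of the 96 genes 95 were placed by symbol. Of them 22 had an annotated antisense exon overlap and 7 shared exon sequence with another gene of the table. Transcripts at 95% identity or more over at least 50% of their length, found with BLAST+ 2.17.0, gave 5 named genes a near-identical partner in the table. For these genes, reads could have been split by the counting.

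The alternatives tried were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter and a stricter filter of 5 CPM in 2 libraries, robust dispersion, and a fit of the compared groups alone. Further ones were the replicate number as a block, covariates for Y-linked expression and stroma markers, both groups without the knockout as reference, fry in place of camera, and leaving out each library of the groups compared. Leaving out the 3 libraries with the lowest totals, the libraries with the highest stroma mean, or Lars2 was added after the data were seen. The edgeR step was tested on simulated counts of 12530 genes. Changed genes were drawn from those with a mean of at least 5 CPM over all libraries, 25 per size and direction. Recovery at lower levels is therefore not known. In the simulated Dnmt1cKO against Cre-negative comparison the edgeR step recovered 84% of 16-fold, 64% of 8-fold, 32% of 4-fold and 4% of 2-fold rises, with 5 false calls among 12330 unchanged genes. Of the falls it recovered 44% of 16-fold, 48% of 8-fold, 16% of 4-fold and 0% of 2-fold ones. In the simulated Dnmt1cKO against Cre-positive control comparison it recovered 64% of 16-fold, 20% of 8-fold and 0% of 4-fold rises, and 40%, 16% and 8% of the falls of these sizes, with 2 false calls. It recovered 0% of 2-fold rises and falls there. In the simulated control comparison, in which no gene was changed, it made 0 calls, which says nothing of its recovery there.

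Of the 91 pairs of libraries, 0 held identical values, and the lowest chi-square per degree of freedom between 2 libraries was 39.4. Figures and searches used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.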

Results

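Gene expression was measured by polyA RNA-seq in the bladder urothelium of C57BL/6; 129S4 mouse embryos at embryonic day 15.5. The urothelium is the epithelium that lines the bladder. The 14 libraries came from Cre-negative littermates (n = 7), Cre-positive controls with 1 floxed Dnmt1 allele (n = 2) and Dnmt1cKO embryos (n = 5), in which Cre expressed from the Shh locus deletes Dnmt1, the maintenance DNA methyltransferase. Each library is 1 lysate of pooled tissue. Total expected counts were 12958881, 3111972, 5972976, 11527617, 8439643, 7871242 and 10870652 in Cre-negative libraries 1 to 7. They were 13131921 and 5731113 in the controls and 3402894, 9573007, 4589475, 4671072 and 2520509 in Dnmt1cKO libraries 1 to 5.

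The first question is how far the targeted genes were changed. Dnmt1 measured 119 ± 58.4 CPM in Cre-negative, 102 ± 6.20 CPM in control and 48.0 ± 44.3 CPM in Dnmt1cKO libraries (SD; n = 7, 2 and 5). Its log2 fold change was -1.31 ± 0.51 against Cre-negative (adjusted p = 0.249) and -1.08 ± 0.68 against the controls (adjusted p = 0.95), neither past the threshold. With the stroma mean as a covariate it fell by 2.59 against Cre-negative (adjusted p = 0.0112, within a range of 0.0112 to 0.544 over the alternatives). Dnmt1cKO libraries 1, 2, 4 and 5 held 9.99, 26.7, 31.2 and 49.1 CPM, and the library labelled Dnmt1cKO 3 held 123 CPM, inside the Cre-negative range of 41.3 to 192 CPM. Dnmt1cKO 3 also had the highest mean of stroma markers of all libraries, 7.42 log2 CPM. Counts are per gene, so exons left on a recombined Dnmt1 allele can still give reads. Shh, the signalling ligand whose locus carries Cre on 1 allele, fell from 267 ± 72.4 CPM in Cre-negative to 43.7 ± 38.1 CPM in Dnmt1cKO libraries (log2 fold change -2.60 ± 0.52, adjusted p = 0.00726). In the controls, which carry the same Shh allele, it stood at 109 ± 66.4 CPM, with adjusted p = 0.723 for Dnmt1cKO against control and 1 for control against Cre-negative. Trp53, which encodes p53, had 36.8 CPM in Cre-negative and 47.9 CPM in Dnmt1cKO libraries (log2 fold change 0.38 ± 0.66, adjusted p = 0.899). The call for Shh was lost with the stroma mean as a covariate (log2 fold change -2.38 ± 0.60, adjusted p = 0.0745), with both groups without the knockout as reference (-1.96 ± 0.51, adjusted p = 0.0946) and without the 3 shallowest libraries (-2.31 ± 0.63, adjusted p = 0.0997). Dnmt1 lies on chromosome 9 from 20907209 to 20959888 on the minus strand. Shh lies on chromosome 5 from 28456815 to 28467256 on the minus strand, where exons of 2 antisense genes overlap it.

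**Figure D1:**
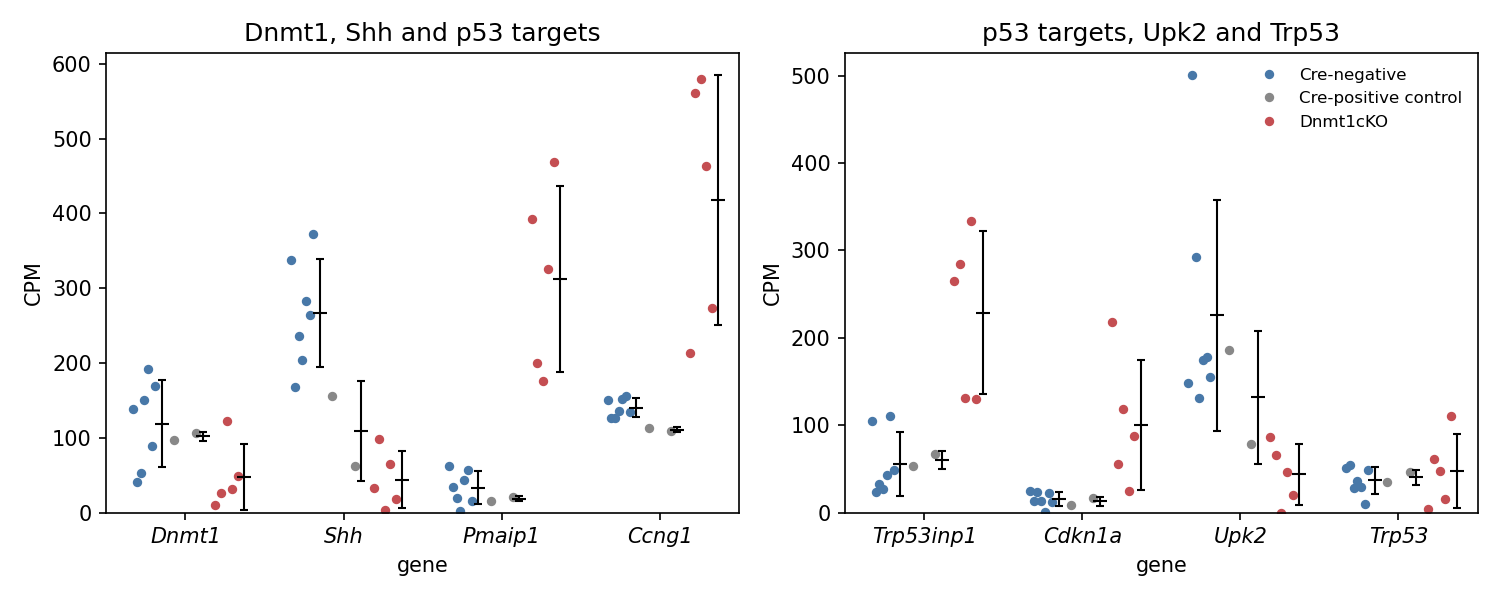
CPM (vertical axes) of Dnmt1, Shh, Trp53, 4 p53 target genes and Upk2 in each library of the 3 groups; bars are the mean ± SD. Pmaip1 averaged 312 CPM in Dnmt1cKO and 33.4 CPM in Cre-negative libraries.

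The comparison of Dnmt1cKO with Cre-negative urothelium asks what differed when Cre and both floxed Dnmt1 alleles were present together. Germline genes and X-linked reproductive homeobox genes were among those that rose most. Rhox9, a homeobox gene of the Rhox cluster, had 0 counts in the 9 other libraries and 172 ± 114 CPM in Dnmt1cKO libraries (n = 5), at least 3580-fold higher than in Cre-negative libraries (adjusted p = 2.12e-08). Rhox6 rose from 0.131 to 714 ± 292 CPM (log2 fold change 12.14 ± 0.52, adjusted p = 1.26e-14) and Rhox5 from 0.0770 to 308 ± 111 CPM (11.64 ± 0.63, adjusted p = 1.86e-12). Trap1a, a tumour antigen gene on the X chromosome, rose from 0.312 to 1009 ± 188 CPM (11.71 ± 0.47, adjusted p = 4e-15). Rhox4a was 2850-fold higher (95% counting interval 788 to 23500, adjusted p = 1.26e-07), Tex13 3610-fold (647 to 143000, adjusted p = 2.34e-06), and Tuba3a, a testis alpha-tubulin gene, 2010-fold (688 to 9770, adjusted p = 3.7e-08). Hist4h4, a histone H4 gene, rose from 2.5 ± 1.24 to 3689 ± 1058 CPM (log2 fold change 10.49 ± 0.42, adjusted p = 4e-15). Its transcript shares a segment of sequence with another raised gene. Rhox4a has near-identical copies among the other Rhox4 genes, and Tuba3a has one in Tuba3b, so that single copies are not resolved.

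Of 13 measured genes of the Rhox and Xlr clusters, 10 rose and 0 fell (13 and 0 adjusted over the list alone), with a median log2 fold change of 6.60 and a camera adjusted p of 9.29e-41. Of 23 measured germline genes silenced by DNA methylation, 11 rose and 0 fell (16 and 1 adjusted over the list alone), with a median of 9.08, or 7.81 with genes at 0 in a group set to their bound, and a camera adjusted p of 1.09e-29. Taf7l, a testis paralog of a general transcription factor subunit, rose from 0.133 to 172 ± 92.1 CPM (log2 fold change 10.08 ± 0.72, adjusted p = 5.64e-10). Dazl, a germ cell RNA-binding protein gene, rose from 0.12 to 97.0 ± 57.4 CPM (9.40 ± 0.93, adjusted p = 2.09e-07). Tuba3b was 2320-fold higher (793 to 11300, adjusted p = 1.18e-08) and Rhox4b 2040-fold (563 to 16800, adjusted p = 2.96e-06). Both list calls held with an estimated correlation (adjusted p = 1.01e-06 for the clusters and 1.81e-05 for the germline genes). A member silent in both other groups, such as Rhox9 or Rhox13, could pass the filter on low counts only through the Dnmt1cKO libraries. Such genes could rise and not fall, so the counts and list p-values favour rises. The library labelled Dnmt1cKO 3, with Dnmt1 at 123 CPM, held Trap1a at 873 CPM and Rhox6 at 517 CPM. On the X chromosome Rhox9 spans 37899097 to 37901770, Rhox6 37826910 to 37829857, Rhox5 37804842 to 37808876, Rhox4a 37265338 to 37270132 and Trap1a 139333683 to 139338169. Hist4h4 spans 136801553 to 136804415 and Tuba3a 125278274 to 125286042 on chromosome 6, and Tex13 was not placed.

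**Figure D2:**
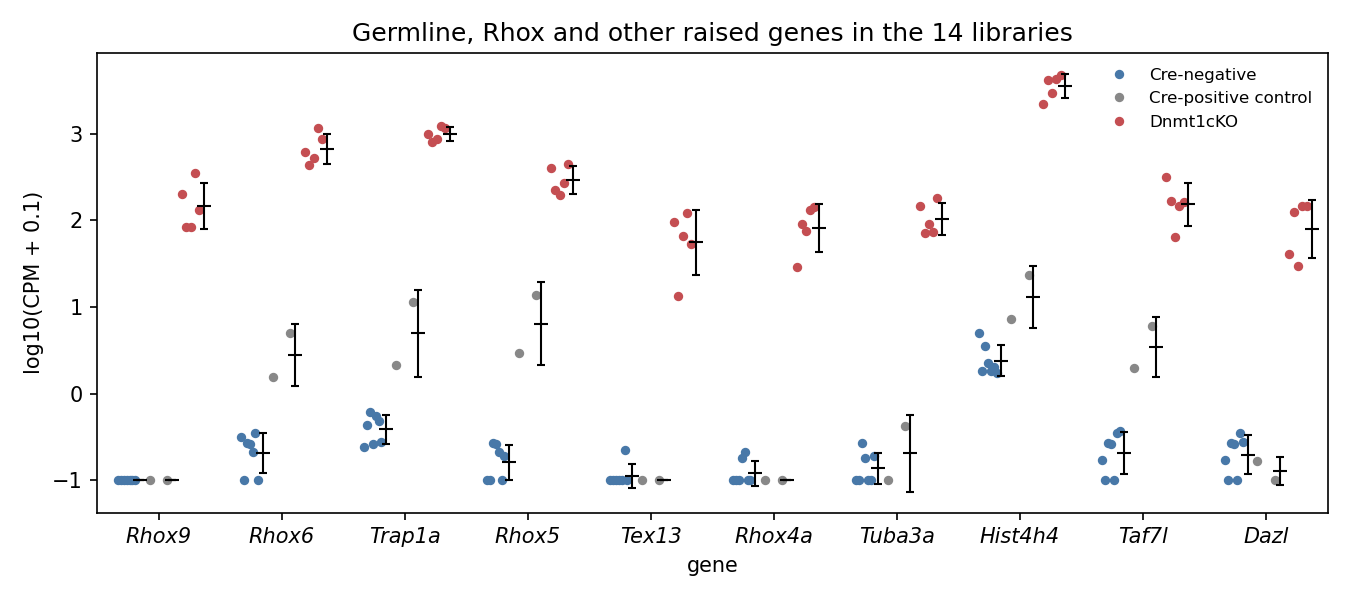
Log10 of CPM plus 0.1 (vertical axis) of 10 raised genes in each of the 14 libraries by group; bars are the mean ± SD of the log10 values. Hist4h4 averaged 3689 CPM in Dnmt1cKO, 15.3 CPM in control and 2.5 CPM in Cre-negative libraries.

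Target genes of p53 were higher in Dnmt1cKO than in Cre-negative urothelium. Pmaip1, which encodes the pro-apoptotic protein Noxa, rose from 33.4 ± 22.2 to 312 ± 124 CPM (log2 fold change 3.22 ± 0.50, adjusted p = 0.000405), with all 5 Dnmt1cKO libraries above the 9 others. Ccng1, cyclin G1, rose from 140 ± 12.6 to 418 ± 167 CPM (1.58 ± 0.27, adjusted p = 0.00138). Trp53inp1, a p53-induced stress protein gene, rose from 55.8 ± 36.9 to 229 ± 93.4 CPM (2.03 ± 0.41, adjusted p = 0.00872) and Cdkn1a, the cell cycle inhibitor p21, from 15.6 ± 8.45 to 101 ± 74.5 CPM (2.69 ± 0.66, adjusted p = 0.0401). Of 22 measured p53 target genes 4 rose and 0 fell (7 and 1 adjusted over the list alone), with a median log2 fold change of 0.53, a camera adjusted p of 4.61e-06 and an adjusted p of 0.012 with an estimated correlation. The cell cycle list (25 genes, camera adjusted p = 0.243) and the list of DNA damage signalling and repair (22 genes, 0.894) did not pass. Ccnd1, cyclin D1, was the 1 cell cycle gene called, at 2.99 CPM in Cre-negative, 87.4 ± 75.1 CPM in control and 63.4 ± 25.2 CPM in Dnmt1cKO libraries (log2 fold change against Cre-negative 4.38 ± 0.98, adjusted p = 0.0211). Ccng1 lost its call with the stroma mean as a covariate (log2 fold change 1.22 ± 0.30, adjusted p = 0.0694) and with the replicate number as a block (1.52 ± 0.38, adjusted p = 0.0743). Ccnd1 lost its call with both groups without the knockout as reference (1.96 ± 0.97, adjusted p = 0.482), without the 3 shallowest libraries (adjusted p = 0.103), without the highest-stroma libraries (0.0615), in the fit of these groups alone (0.0691) and without Cre-negative 7 (0.0539). Cdkn1a lost its call in 7 of the other settings (highest adjusted p = 0.319, with the block) and when any 1 of Cre-negative 1, 2, 3, 4, 6 or 7 or Dnmt1cKO 1, 3 or 5 was left out, with the highest adjusted p, 0.155, without Dnmt1cKO 1.

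Among imprinted genes, 3 were called higher, and 15 of the 22 measured had a positive log2 fold change. Zim1 (334 counts in Cre-negative and 1 in Dnmt1cKO libraries) and Magel2 (48 and 0) went the other way without a call. Peg10 rose from 18.3 ± 11.9 to 628 ± 218 CPM (log2 fold change 5.09 ± 0.54, adjusted p = 7.03e-07). Mest rose from 27.0 ± 14.8 to 227 ± 251 CPM (3.07 ± 0.61, adjusted p = 0.00712) and Peg3 from 304 ± 112 to 702 ± 161 CPM (1.21 ± 0.27, adjusted p = 0.0211). Of 22 measured members 3 rose and 0 fell (4 and 2 adjusted over the list alone), with a median of 0.91 and a camera adjusted p of 0.00086, and the list had an adjusted p of 0.223 with an estimated correlation and 0.311 with the stroma mean as a covariate. Mest stood at 219 ± 192 CPM in the controls, and its call was lost with the stroma mean as a covariate (log2 fold change 1.17 ± 0.51, adjusted p = 0.421), with both groups without the knockout as reference (1.56 ± 0.62, adjusted p = 0.384), with voom (adjusted p = 0.125) and with the block (0.16). That of Peg3 was lost at a log2 fold change of 1.13 ± 0.29 with the same covariate (adjusted p = 0.0879) and of 1.16 ± 0.28 without Cre-negative 1 (adjusted p = 0.0529), against 1.21 ± 0.27 with neither, and also with both groups without the knockout as reference (adjusted p = 0.0827) and without the 3 shallowest libraries (0.0987). Uhrf1, the partner of Dnmt1 at replicating DNA, had 144 CPM in Cre-negative and 233 CPM in Dnmt1cKO libraries (adjusted p = 0.239), and the DNA methylation machinery list had a camera adjusted p of 0.356. The clustered beta protocadherins (0 of 7 called by edgeR, camera adjusted p = 0.979) had a median of -2.02, or -1.51 with bounds, against an upward test direction. The interferon response list did not pass (adjusted p = 0.327).

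Markers of intermediate and superficial urothelium, the differentiated layers, fell as a list against Cre-negative (median log2 fold change -0.43, camera adjusted p = 0.0264), with an adjusted p of 0.649 with an estimated correlation. With the stroma mean as a covariate the direction of this list turned upward (adjusted p = 0.778). Of its 22 measured genes 0 were called over all genes by edgeR, 2 were lower adjusted over the list alone, and 5 had a positive log2 fold change. Upk2, a uroplakin of the apical plaque, had 226 ± 132 CPM in Cre-negative, 132 ± 76.4 CPM in control and 43.6 ± 34.6 CPM in Dnmt1cKO libraries (log2 fold change against Cre-negative -2.37 ± 0.68, adjusted p = 0.0967, or 0.0224 without Dnmt1cKO 3). In the same libraries stroma markers averaged 5.03 log2 CPM in Dnmt1cKO and 3.16 in Cre-negative. Krt7, a simple keratin, had 1720, 1072 and 970 CPM (adjusted p = 0.119). Among basal markers Krt5 had 159 ± 55.8 CPM in Cre-negative and 281 ± 76.7 CPM in Dnmt1cKO libraries (adjusted p = 0.184) and Trp63 178 ± 82.8 and 84.2 ± 45.9 CPM (adjusted p = 0.255), and the list did not pass (camera adjusted p = 0.243). The 12 measured Wolffian duct markers, genes of the epithelial duct that gives rise to the ureteric bud, had a median of -0.58, or -0.23 with bounds (adjusted p = 0.31). The second value includes Pax8, with 0 counts in Dnmt1cKO and 4 in Cre-negative libraries. Its log2 bound of 1.46 lies above 0 and sets no direction. Of the 12 markers, Gfra1, a co-receptor for GDNF, had 94.3 CPM in Cre-negative and 28.6 CPM in Dnmt1cKO libraries (adjusted p = 0.258). Wnt11 had 18.1 and 1.31 CPM (adjusted p = 0.29, or 0.017 without Dnmt1cKO 5), and Cdh16 had 0.604 CPM in Cre-negative and 0 in Dnmt1cKO libraries. In the Hedgehog list the mean was 0.24 and the median -0.01, and DNA damage genes (0.06) and Y-linked genes (-0.11) had medians whose sign was opposite to the test direction. Shh was the 1 lower gene in the urogenital sinus and prostate bud list (adjusted p = 0.0972) and in the Hedgehog pathway list (adjusted p = 0.979).

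Transcripts of other cell types also differed between these groups. Stroma and smooth muscle markers rose as a list (2 of 18 called, 12 adjusted over the list alone, median log2 fold change 2.21, camera adjusted p = 6.31e-11), with an adjusted p of 0.223 with an estimated correlation. Tagln, a smooth muscle actin-binding protein gene, rose from 11.5 to 145 ± 179 CPM (3.65 ± 0.77, adjusted p = 0.0129). Myh11, smooth muscle myosin heavy chain, rose from 54.7 to 386 ± 374 CPM (2.82 ± 0.64, adjusted p = 0.0242), and the controls held 142 CPM of Tagln and 554 CPM of Myh11. Erythroid markers rose as a list (5 of 7 adjusted over the list alone, 0 over all genes, median 1.79, camera adjusted p = 0.00202), with an adjusted p of 0.271 with an estimated correlation and 0.617 with the stroma mean as a covariate. The mean log2 CPM of the stroma markers was 3.16 ± 1.21 in Cre-negative, 6.32 ± 1.19 in control and 5.03 ± 2.05 in Dnmt1cKO libraries (two-sided exact permutation p = 0.0833 for Dnmt1cKO against Cre-negative, adjusted p = 0.185). The lists for mesothelium (adjusted p = 0.132), endothelium (0.606), immune cells (0.253), neural and glial cells (0.306), immediate early and heat shock genes (0.126), ribosomal proteins (0.327) and Y-linked genes (0.733) did not pass. Within them Jun, an immediate early transcription factor gene, rose from 20.3 to 135 ± 37.8 CPM (2.73 ± 0.61, adjusted p = 0.0211; 104 CPM in the controls). Uchl1, a neuronal ubiquitin hydrolase gene, fell from 502 to 95 ± 86.7 CPM (-2.40 ± 0.58, adjusted p = 0.0377). With both groups without the knockout as reference the calls of Tagln (log2 fold change 1.84 ± 0.78, adjusted p = 0.396), Myh11 (1.15 ± 0.65, adjusted p = 0.569), Jun (1.55 ± 0.63, adjusted p = 0.385) and Uchl1 (-2.12 ± 0.58, adjusted p = 0.131) were lost. With voom those of Tagln (adjusted p = 0.231) and Myh11 (0.102) were lost, and with the stroma mean as a covariate those of Uchl1 (0.254) and Jun (0.0528). Tagln lost its call without Dnmt1cKO 4 (adjusted p = 0.131), Jun without Cre-negative 3 (adjusted p = 0.0504), and Myh11 without any 1 of Cre-negative 1, 3, 6 or 7 or Dnmt1cKO 3 or 4 (highest adjusted p = 0.115, without Dnmt1cKO 3). Uchl1 lost it without any 1 of Cre-negative 1, 2, 3, 5, 6 or 7 or Dnmt1cKO 1, 2 or 5 (highest adjusted p = 0.104, without Dnmt1cKO 5).

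**Figure D3:**
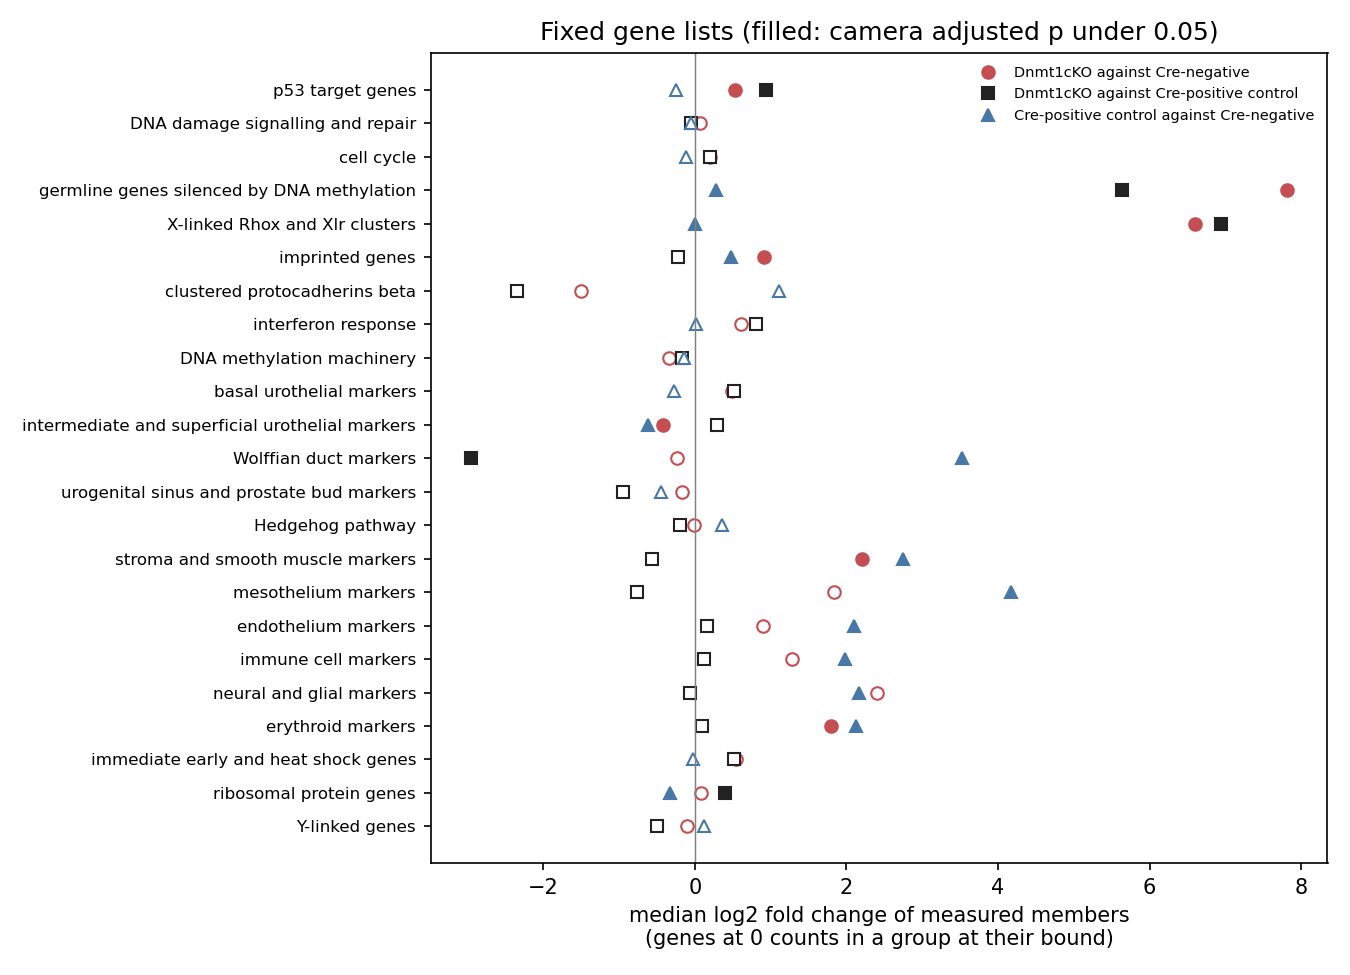
Median log2 fold change (horizontal axis) of each of the 23 gene lists in Dnmt1cKO against Cre-negative (circles), Dnmt1cKO against Cre-positive control (squares) and control against Cre-negative (triangles), with genes at 0 in a group set at their bound; filled symbols have a camera adjusted p under 0.05. The Rhox and Xlr clusters had medians of 6.60, 6.94 and 0 in that order. The Wolffian duct circle includes a bound for Pax8 that lies above 0 and sets no direction.

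By edgeR 119 genes rose and 24 fell against Cre-negative among 13011 tested, with 867 higher and 915 lower at an unadjusted p under 0.05. DESeq2 called 332 higher and 235 lower genes, and voom 162 higher and 292 lower. Of the 119 higher genes 21 had 0 counts in every Cre-negative library. Over the 13011 tested genes, all 5 Dnmt1cKO libraries stood above the 9 others in 89 and below them in 85, where chance gives 0.05% of genes in each direction. With the stroma mean as a covariate 81 genes were called, 76 of them among the 143, and 93 were called without Cre-negative 7 and 238 without Dnmt1cKO 2.

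The comparison of Dnmt1cKO with Cre-positive controls holds Cre and the altered Shh allele alike in both groups and leaves the second floxed Dnmt1 allele as the difference. Germline and Rhox genes were again higher: 23 genes rose, and all 23 had also risen against Cre-negative. Rhox9 was at least 1180-fold higher (adjusted p = 0.000429), Rhox4a at least 646-fold (adjusted p = 0.00204) and Tex13 at least 483-fold (adjusted p = 0.0161). Hist4h4 rose from 15.3 ± 11.4 to 3689 ± 1058 CPM (log2 fold change 7.93 ± 0.68, adjusted p = 1.8e-07) and Rhox6 from 3.15 ± 2.41 to 714 ± 292 CPM (7.87 ± 0.76, adjusted p = 7.21e-07). Trap1a rose from 6.62 ± 6.43 to 1009 ± 188 CPM (7.28 ± 0.68, adjusted p = 6.58e-07) and Rhox5 from 8.30 ± 7.73 to 308 ± 111 CPM (5.23 ± 0.80, adjusted p = 0.000884). Taf7l rose with a log2 fold change of 5.47 ± 1.01 (adjusted p = 0.00962), and Tuba3a was 996-fold higher (276 to 8230, adjusted p = 0.00404) and Dazl 2080-fold (374 to 82400, adjusted p = 0.00306). The germline list (4 of 23 called, 9 higher and 1 lower adjusted over the list alone, median 6.88, or 5.64 with bounds, camera adjusted p = 5.69e-21) held with an estimated correlation (adjusted p = 3.52e-05). So did the Rhox and Xlr clusters (3 of 13, 11 adjusted over the list alone, median 6.94, camera adjusted p = 2.94e-34, adjusted p = 3.38e-06 with an estimated correlation). Here too, members silent in both other groups were measured only through the Dnmt1cKO libraries, which favours rises.

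The p53 target genes also rose as a list against the controls (median log2 fold change 0.94, camera adjusted p = 1.59e-06, adjusted p = 0.00981 with an estimated correlation), while fry gave an adjusted p of 0.0914. Of the 22, edgeR called 0 over all genes, DESeq2 2 and voom 1, while 5 were higher and 1 lower adjusted over the list alone. Pmaip1 had 18.7 ± 3.77 CPM in control and 312 ± 124 CPM in Dnmt1cKO libraries (log2 fold change 4.06 ± 0.89, adjusted p = 0.0596) and Ccng1 111 ± 2.92 and 418 ± 167 CPM (1.91 ± 0.44, adjusted p = 0.0812). Wolffian duct markers were lower as a list than in the controls (median -2.95, 3 of 12 lower adjusted over the list alone, 0 over all genes, camera adjusted p = 6.9e-05), with an adjusted p of 0.0574 with an estimated correlation. Against Cre-negative the list was raised in the controls (median 3.53, camera adjusted p = 0.000138) and did not pass in Dnmt1cKO libraries (camera adjusted p = 0.31). The high levels thus lay in the controls. Among them Cdh16, a kidney and duct cadherin gene, had 12.1 and 60.5 CPM in the controls and 0 in the 5 Dnmt1cKO libraries. Calb1, a calcium-binding protein gene, had 6.01 and 35.6 CPM in the controls and 0.791 ± 1.71 CPM in Dnmt1cKO libraries (adjusted p = 0.812). Ribosomal protein genes rose as a list (median 0.40, camera adjusted p = 4.74e-05), with an adjusted p of 0.723 with an estimated correlation. Stroma markers did not differ past the threshold (median -0.57, adjusted p = 0.618). The mean log2 CPM of mesothelium markers was 4.63 ± 0.80 in the controls, with a difference of -2.13 for Dnmt1cKO minus control, and that of endothelium markers was 1.91 ± 0.62 in the controls and -0.17 ± 0.86 in Dnmt1cKO libraries. For both the two-sided exact permutation p was 0.0476, the smallest that 21 splits allow (adjusted p = 0.167).

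The other lists did not pass in this comparison. Imprinted genes (-0.23), DNA damage genes (-0.05) and endothelium (0.16), immune cell (0.12) and erythroid markers (0.10) had medians whose sign was opposite to the test direction. No gene fell by edgeR (0 of 13011, with 680 lower at an unadjusted p under 0.05), while DESeq2 called 25 and voom 173 lower genes. With n = 2 controls the number called rested on single libraries: 6 genes without control 1, 9 without control 2 and 37 without Dnmt1cKO 2. Rhox5 (adjusted p = 0.155) and Tuba3a (0.323) lost their calls without control 1, Rhox4a without control 1 (0.208) or control 2 (0.106), and Tex13 without control 1 (0.762), control 2 (0.421), Dnmt1cKO 1 (0.0551) or Dnmt1cKO 4 (0.0929). The 23 shared genes use the same Dnmt1cKO libraries in both comparisons. With these split between the comparisons in 10 ways, 22 to 34 genes were shared, against at most 0.445 expected for independent lists. Both parts had the same genotype and were tested in 1 fit, so any effect of the group gives more than 0.445 shared genes. No conclusion is drawn from that gap.

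The controls were compared with Cre-negative littermates to see what Cre, the changed Shh allele and recombination of at most 1 Dnmt1 allele went with. Whether the Cre-negative littermates carried floxed Dnmt1 alleles is not given here. Of the 119 genes raised in Dnmt1cKO libraries 7 were also called higher in the controls, at low levels, while 22 of the 40 with 0 to 3 counts in Cre-negative libraries had 0 in both controls. Rhox5 rose from 0.0770 CPM in Cre-negative to 8.30 ± 7.73 CPM (log2 fold change 6.41 ± 0.64, adjusted p = 4.76e-06). Trap1a rose from 0.312 to 6.62 ± 6.43 CPM (4.43 ± 0.47, adjusted p = 8.96e-06) and Rhox6 from 0.131 to 3.15 ± 2.41 CPM (4.27 ± 0.56, adjusted p = 0.000255). Hist4h4 rose from 2.5 to 15.3 ± 11.4 CPM (2.56 ± 0.39, adjusted p = 0.0025) and Taf7l from 0.133 to 3.93 ± 2.92 CPM (4.61 ± 0.72, adjusted p = 0.0027). Tuba3b was 36.4-fold higher (11.5 to 185, adjusted p = 0.0148), and Hp, which encodes haptoglobin and was chosen after its values were seen, at least 140-fold higher (adjusted p = 0.0148). These 7 genes made up the calls, and all 7 had also risen in Dnmt1cKO against Cre-negative. Both comparisons share the Cre-negative libraries and 1 fit, so the overlap is partly built in and no conclusion is drawn from it. Rhox9, Rhox4a and Tex13 had 0 counts in both controls. EdgeR called 0 lower genes (23 at an unadjusted p under 0.05), DESeq2 8 and voom 0. The call rested on single libraries: 2 genes were called without control 2 and 11 without control 1, and voom and the fit of these groups alone kept 0 of the 7. In the fit of these groups alone the log2 fold changes were 6.53 for Rhox5, 4.40 for Trap1a and 4.75 for Taf7l. Without control 2 Hist4h4 (adjusted p = 0.926), Taf7l (0.689) and Rhox6 (0.128) lost their calls.

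Markers of several other cell types were higher in the controls. The stroma list rose (0 of 18 called over all genes by edgeR, 8 adjusted over the list alone, median 2.74, camera adjusted p = 1.43e-24) and passed with an estimated correlation (adjusted p = 0.0474). Mesothelium markers rose (median 4.17, 3 of 6 adjusted over the list alone, camera adjusted p = 0.000159, adjusted p = 0.0309 with an estimated correlation). Lists that rose with camera and not with an estimated correlation were erythroid (median 2.12, camera adjusted p = 5.21e-08, adjusted p = 0.059 with an estimated correlation) and immune cell markers (median 1.98, camera adjusted p = 0.00139, adjusted p = 0.0612 with an estimated correlation). The same held for endothelium markers (median 2.10, camera adjusted p = 0.00968, adjusted p = 0.147 with an estimated correlation) and neural and glial markers (camera adjusted p = 0.017, adjusted p = 0.353 with an estimated correlation). Wolffian duct markers also rose with camera (median 3.53, 5 of 12 adjusted over the list alone, camera adjusted p = 0.000138, adjusted p = 0.059 with an estimated correlation). So did imprinted genes (median 0.48, camera adjusted p = 2.97e-05, adjusted p = 0.0612 with an estimated correlation). The germline list (2 of 23 called, median 0.28, camera adjusted p = 0.00149, adjusted p = 0.059 with an estimated correlation) and the Rhox and Xlr clusters (2 of 13, median 0, camera adjusted p = 2.97e-05, adjusted p = 0.0309 with an estimated correlation) rose as well, the clusters with an adjusted p of 0.0539 with the replicate number as a block. With the stroma mean as a covariate the calls of imprinted genes (adjusted p = 0.979), Wolffian duct (0.717) and immune cell markers (0.49) were lost, and the erythroid (0.979), endothelium (0.941) and neural and glial lists (0.345) turned direction.

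Markers of intermediate and superficial urothelium fell as a list in the controls (median -0.62, 1 of 22 positive, camera adjusted p = 5.21e-08, adjusted p = 0.104 with an estimated correlation), and with the stroma mean as a covariate the direction turned upward (adjusted p = 0.827). Ribosomal protein genes also fell (median -0.33, camera adjusted p = 0.000138, adjusted p = 0.549 with an estimated correlation). The p53 target genes did not pass (median -0.26, adjusted p = 0.363), and neither did the lists not named for this comparison. The means of the cell cycle (0.08), basal (0.26) and urogenital sinus lists (0.05) were positive against negative medians, that of the interferon list (-0.47) was negative against a positive median, and the immediate early list had a median of -0.03 against an upward test direction. The stroma mean was 5.48 and 7.17 in the controls, both above the 7 Cre-negative libraries (two-sided exact permutation p = 0.0278, the smallest that 36 splits allow, adjusted p = 0.167).

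**Figure D4:**
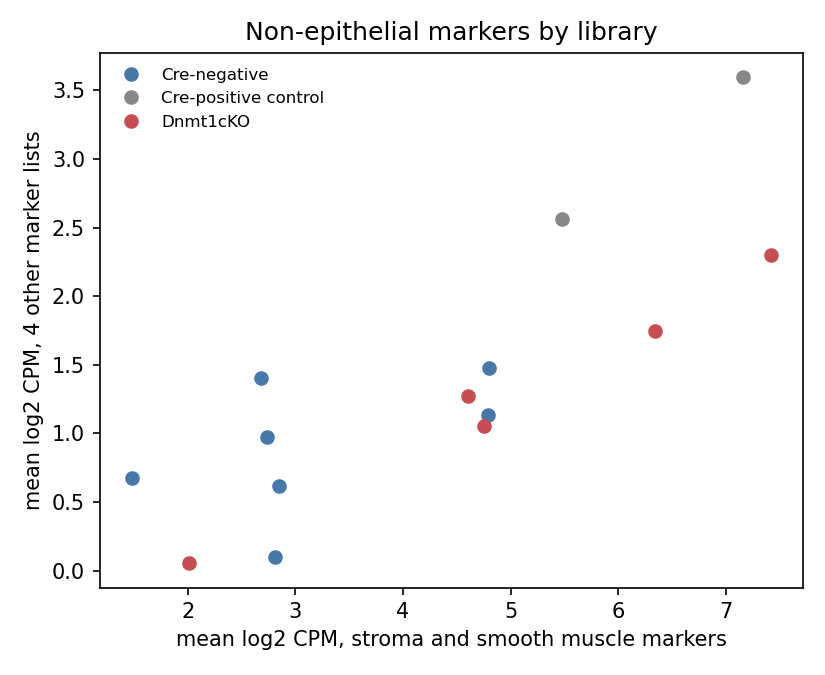
Mean log2 CPM of stroma markers (horizontal axis) against the mean of 4 other marker lists, namely mesothelium, endothelium, immune, and neural and glial (vertical axis), 1 point per library. The highest stroma mean, 7.42, belongs to Dnmt1cKO 3, and the controls hold the highest means on the vertical axis, 2.56 and 3.60.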

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

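The test of stroma carry-over was fixed before its result was seen, and the tests of other splits of the libraries, of a uniform share of Dnmt1cKO RNA and of misassigned reads were chosen only after the results they address were seen. The outlier check covered 226 sets of values: named genes, list means and measures of whole libraries within Cre-negative or Dnmt1cKO. In 36 sets the highest or lowest library had a gap to the nearest other above Dixon's 95% critical value. Chance would give about 11.3 if the sets were independent and normally distributed, which genes with many zeros are not. Gaps of genes were taken on log2 CPM with a prior count of 2, while gene values below are CPM. Sets whose highest library held fewer than 3 counts were left out, a floor set after the first pass. The library labelled Dnmt1cKO 3 and Cre-negative 2 each had 7 of them, Cre-negative 4 had 5 and Dnmt1cKO 5 had 4.

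In Dnmt1cKO 3, Krt14 was 0.241 CPM (others 24.9 to 33.5), Upk2 0 (20 to 86.2), Calb1 3.85 (0 to 0.104), Hhip 35.8 (0 to 0.483), Bnc1 51.0 (0 to 0.435), Ptprc 25.3 (0 in the others) and Kdm5d 0.962 (25.1 to 78.0). In Dnmt1cKO 5, Trp63 was 12.6 CPM (63.1 to 117), Wnt11 6.52 (0 in the others) and Hoxb13 14.4 (0 in the others), and Lars2, its most abundant gene, took 4.81% of counts (top genes of the others 0.719% to 0.952%). Dnmt1cKO 1 held 0 CPM of Gfra1 (20.9 to 62.8), Dnmt1cKO 2 held 6.46 CPM of Xrcc2 (0 to 0.241) and 849 CPM of Rpl8 (1310 to 1390), and Dnmt1cKO 4 held 13.8 CPM of Atf3 (0 to 0.435).

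Cre-negative 2 was low in the Y-linked genes Uty (0 CPM, others 19.5 to 100), Eif2s3y (0.341, others 50.1 to 80.0), Kdm5d (0.341, others 22.5 to 86.0) and Ddx3y (1.71, others 91.8 to 162). Its Y-linked mean was -0.60 (5.56 to 6.45), its Rab27b 322 CPM (635 to 851), and its most abundant gene took 1.05% of counts (at most 0.785% in the others). Cre-negative 4 held 2.18 CPM of Pcdhb6 (0 to 0.341), 0.725 of Rsad2 (0 to 0.0722), 1.69 of Hhip (0 to 0.173) and 0.967 of Csf1r (0 to 0.127), and a Wolffian duct mean of 2.52 (1.36 to 1.81). Cre-negative 1 held 2.82 CPM of Pcdhb3 (0 in the others), 2.02 of Bnc1 (0 to 0.341) and 1.81 of Hbb-bt (17.7 to 48.3). Cre-negative 5 held 1.03 CPM of Cdkn1a (11.7 to 24.9) and 0 of Xrcc2 (5.80 to 22.3). Cre-negative 6 held 9.56 CPM of Trp53 (28.7 to 54.6) and 36.1 of Msln (76.2 to 131), and Cre-negative 7 held 0.994 of Pcdhb17 (0 in the others) and 1.17 of Gpm6a (0 to 0.0806).

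Of 100 drawn splits of the 12 Dnmt1cKO and Cre-negative libraries into groups of 5 and 7, the real one included, 1 gave as many calls as the real 143. The highest of the other splits gave 34, in a split whose group of 5 held 0 Dnmt1cKO libraries. The real division thus gave the most calls of the 100 drawn. All other splits put Dnmt1cKO and Cre-negative libraries together in 1 group or both, which widens the spread there. The count therefore cannot tell loss of Dnmt1 from another difference between libraries that goes with the labels.

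Stroma markers were higher in the controls than in Cre-negative libraries, and high in some Dnmt1cKO libraries. RNA from stroma carried over with the urothelium may account for this. Within groups the stroma mean went with the mean of mesothelium, endothelium, immune and neural markers (Pearson r = 0.837, permutation p = 0.00275; Spearman rho = 0.71, permutation p = 0.0145; 14 libraries; these 2 are the whole family). The value of r lay between 0.725 and 0.893 with each library left out and was 0.642 without Dnmt1cKO 3 and Dnmt1cKO 1, the farthest from the median. Col1a1, the most abundant of the stroma markers named, averaged 2072 CPM in the controls and 221 CPM in Cre-negative libraries, though the trypsin separation was meant to remove stroma, and a difference that goes with genotype stays open and was not tested.

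Some genes raised in Dnmt1cKO libraries had low counts in the Cre-positive controls. The tests below used the 40 raised genes with 0 to 3 summed Cre-negative counts and speak for these alone. Rhox5, Rhox6, Trap1a, Hist4h4 and Taf7l, called in the controls, had more Cre-negative counts and were left out. For the 40 genes the counts argue against 1 uniform share of Dnmt1cKO RNA in the controls as the whole cause. Of them 22 were at 0 in both controls, where 2000 simulations of a share of 1.22% gave 2 to 11 (median 6). Rhox9 would have had 43.1 counts at that share and had 0, though a single pool of another make-up could still give the counts. The same 22 genes argue against reads misassigned between libraries at 1 rate as the whole cause, since simulations of reads in proportion to the counts of all Dnmt1cKO libraries gave 0 to 2 such genes, and to those of any 1 Dnmt1cKO library 1 to 14, and the 28 genes with no near-identical copy, 14 of them at 0, also lay above their simulations. An earlier form of the misassignment test, on whether the 7 genes called in the controls kept their calls (7 with DESeq2, 0 with voom), had decided nothing; before these tests, summed levels relative to Dnmt1cKO were compared in 2 forms, over 33 fixed list genes (2.49% and 5.11% in the controls, 1.73% to 4.31% in Cre-negative) and over 23 called genes (2.87% and 3.53%, 2.38% to 3.70%), both overlapping, and expression with 1 floxed Dnmt1 allele stays open as untested.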

How the results depend on the processing

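Leaving out the 3 shallowest libraries, those with the highest stroma mean (control 2 and Dnmt1cKO 3) or Lars2 was chosen after the data were seen, and the other alternatives before. Where a value moved the cause was not tested, except that leaving out libraries or groups lowers the number of samples. RLE and upper-quartile scaling, the stricter filter, robust dispersion, the Y-linked covariate and leaving out Lars2 or the 3 shallowest libraries kept the counts of all 3 comparisons within 1.5 times. The genes behind these counts changed more: without the 3 shallowest libraries 94 of the 143 calls against Cre-negative were kept. The same setting kept 17 of the 23 calls against the controls and 5 of the 7 for the controls. Directions of named genes that had been called did not reverse in any alternative. Medians of all genes shifted by over 0.1 against the controls with upper-quartile factors (-0.12), voom (-0.78) and the block (-0.38), and against Cre-negative with voom (-0.34), the stroma covariate (-0.21) and the block (-0.42). For the controls against Cre-negative voom gave a median of 0.15.

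For Dnmt1cKO against Cre-positive control (23 genes), DESeq2 called 113, voom 232, and 13 were called without the highest-stroma libraries. Leaving out 1 library gave 6 (without control 1) to 37 (without Dnmt1cKO 2), with 9 without control 2. For Dnmt1cKO against Cre-negative (143 genes), DESeq2 called 567, voom 454, no filter 249, the fit of these groups alone 86, the stroma covariate 81, and both groups without the knockout as reference 67. Leaving out 1 library gave 93 (without Cre-negative 7) to 238 (without Dnmt1cKO 2), and without Dnmt1cKO 3 there were 127, with 108 of the 143 kept. For control against Cre-negative (7 genes), DESeq2 called 21, voom 40, no filter 25, the stroma covariate 4, and leaving out the highest-stroma libraries 1. Leaving out 1 library gave 2 (without control 2) to 11 (without control 1), and a control left alone was assumed to vary like the other groups.

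Replicate numbers showed no pairing of libraries: over 9 same-numbered pairs residuals correlated at -0.161 to 0.103, and 1 of 12 libraries correlated best with its own number. With the number as a block, 75 genes were called against Cre-negative (70 of the 143 kept), 18 against the controls (16 of the 23 kept) and 19 for the controls (3 of the 7 kept).

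Dnmt1 fell past the threshold with the stroma covariate, at -2.59 (adjusted p = 0.0112), and its adjusted p against Cre-negative ran from 0.0112 to 0.544 over the alternatives. Leaving out 1 library gave -2.00 to -1.05 against Cre-negative and -1.78 to -0.82 against the controls.

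With the stroma mean as a covariate 7 list tests turned direction: intermediate and superficial urothelium against Cre-negative (adjusted p = 0.778) and in the controls (0.827), and endothelium (0.941), neural and glial (0.345) and erythroid markers (0.979) in the controls. The others were the stroma list itself (0.0488 for Dnmt1cKO against the controls, 0.551 for the controls), where the test is void since the list made the covariate. Of 69 list tests, 15 fell short with an estimated correlation, 9 with fry and 10 with its mixed test. Those with fry were p53 target and ribosomal protein genes against the controls, imprinted genes and intermediate and superficial, stroma and erythroid markers against Cre-negative, and intermediate and superficial, neural and glial and ribosomal protein genes in the controls. Calls of members without the highest-stroma libraries were 3 for p53 target genes, 12 for germline genes silenced by DNA methylation and 9 for the X-linked Rhox and Xlr clusters against Cre-negative. Without the 3 shallowest libraries they were 3, 10 and 8. Pmaip1, Trp53inp1 and Peg10 kept their calls against Cre-negative in all alternatives. The 2520509 counts of the shallowest library put 3 counts at 1.19 CPM of its unscaled total, so a count of 0 in it allows a level of up to 1.19 CPM on that scale. With TMM scaling (factor 0.913 in this library) the limit is higher.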

Other observations

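The genes in this part and the tests of chromosomes and of a shared segment were chosen after the values were seen. The 119 genes higher in Dnmt1cKO than in Cre-negative libraries held others outside the fixed naming rule. Stra8, a gene of meiotic entry, was 1470-fold higher (95% counting interval 262 to 58000, adjusted p = 0.00726), and Sohlh2, a germ cell transcription factor gene, 1310-fold (448 to 6370, adjusted p = 1.42e-05). Mnd1, which encodes a meiotic recombination protein, rose from 24.6 ± 11.3 to 271 ± 198 CPM (log2 fold change 3.47 ± 0.50, adjusted p = 0.000106). Dppa5a, a gene expressed in pluripotent cells, was 2120-fold higher (380 to 83900, adjusted p = 0.00169), Tcstv1 1130-fold (202 to 44800, adjusted p = 0.0211), and Zscan4f, which has near-identical copies, went from 0.0945 to 27.6 ± 29.8 CPM (adjusted p = 0.0249). Dppa5a has a near-identical partner in Pigp, so that its reads are not fully resolved. Tcstv1 lost its call without any 1 of Cre-negative 1, 3, 4, 5 or 7 or Dnmt1cKO 4 (highest adjusted p = 0.0674, without Cre-negative 5) and Zscan4f without any 1 of Cre-negative 1, 3, 4 or 7 or Dnmt1cKO 1 or 4 (highest adjusted p = 0.0796, without Dnmt1cKO 1). With the replicate number as a block these 2, Stra8 (adjusted p = 0.39) and Dppa5a (0.123) lost their calls. Rbmy, a Y-linked spermatogenesis gene, rose from 0.130 to 166 ± 127 CPM (9.96 ± 1.02, adjusted p = 4.25e-07). Of 115 higher genes placed on a chromosome, 23 lay on X, which held 454 of 12395 tested genes (odds ratio 6.87, two-sided Fisher's exact p = 2.15e-11, adjusted p = 4.51e-10), and 4 of the 11 tested Y genes were among them (adjusted p = 2.32e-05), while chromosome 2 held 1 of the 115 against 984 of the 12395 (odds ratio 0.101, adjusted p = 0.0101). Of the 4 on Y, Rbmy, Gm21677 and Gm21708 are near-identical to each other, so that single copies are not resolved and the count holds fewer independent loci. Genes of a clustered family are not independent of each other. Genes silent in both other groups were tested only because Dnmt1cKO libraries expressed them, so the tested totals depend on the rise itself.

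Krt4, a keratin of non-cornified stratified epithelia, rose from 454 ± 152 to 1113 ± 250 CPM (log2 fold change 1.29 ± 0.26, adjusted p = 0.00872). Sprr2a2, a small proline-rich protein gene, rose from 18.0 ± 5.24 to 173 ± 65.5 CPM (3.26 ± 0.42, adjusted p = 1.6e-05), and it has a near-identical partner in Sprr2a1, from which it is not resolved. Ly6d rose from 89.1 ± 48.3 to 270 ± 96.1 CPM (1.60 ± 0.40, adjusted p = 0.0496). Gsto1, a glutathione transferase gene, rose from 157 ± 36.4 to 474 ± 82.3 CPM (1.59 ± 0.25, adjusted p = 0.000492). Among the 24 lower genes Wnt4, a signalling ligand, fell from 315 ± 90.3 to 88.6 ± 48.1 CPM (-1.83 ± 0.35, adjusted p = 0.00503), with 156 ± 48.6 CPM in the controls. Igfbp5, an IGF-binding protein gene, fell from 2007 ± 433 to 850 ± 464 CPM (-1.24 ± 0.29, adjusted p = 0.0311) and Ecm1 from 141 ± 92.8 to 2.08 ± 4.38 CPM (-5.88 ± 0.99, adjusted p = 0.00101). Cldn1, a tight junction claudin gene, had 16.5 ± 10.6 CPM in Cre-negative and 0 counts in Dnmt1cKO libraries, at least 131-fold lower (adjusted p = 0.0371). With every library drawn down at random to 2520493 counts, 9902 ± 850 genes had a count in Dnmt1cKO and 10911 ± 923 in Cre-negative libraries. The two-sided exact permutation p of that difference was 0.0884 (adjusted p = 0.185). Whether zeros such as that of Cldn1 go with it was not tested. Krt4 lost its call without the 3 shallowest libraries (log2 fold change 1.08 ± 0.31, adjusted p = 0.119) and Wnt4 with the stroma mean as a covariate (-1.53 ± 0.36, adjusted p = 0.0522) and with both groups without the knockout as reference (-1.32 ± 0.35, adjusted p = 0.107). Ly6d lost it without any 1 of Cre-negative 1, 3, 4, 5, 6 or 7 or Dnmt1cKO 1, 3, 4 or 5 (highest adjusted p = 0.13, without Dnmt1cKO 4) and Igfbp5 without any 1 of Cre-negative 1, 4, 5, 6 or 7 or Dnmt1cKO 1, 3, 4 or 5 (highest adjusted p = 0.1, without Dnmt1cKO 5). Cldn1 lost it without any 1 of Cre-negative 1, 3, 4, 5, 6 or 7 or Dnmt1cKO 2, 3, 4 or 5 (highest adjusted p = 0.0942, without Cre-negative 1), and the log2 fold change of Ecm1 was -9.82 without Dnmt1cKO 2.

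With a call against Cre-negative alone the 8 largest rises take in Hp and also Asz1, a germ cell gene (at least 1210-fold higher, adjusted p = 6.73e-05), Rpl39l, a ribosomal protein gene paralog (at least 995-fold, adjusted p = 0.000221), and Rhox2d, which has near-identical copies (at least 767-fold, adjusted p = 0.00286). Rhox2d lost its call with the replicate number as a block (adjusted p = 0.0658) and without the 3 shallowest libraries (adjusted p = 0.0638). Of the 8 largest falls so chosen, Tbc1d8 fell from 34.1 ± 12.1 to 0.215 ± 0.361 CPM (log2 fold change -6.93 ± 1.31, adjusted p = 0.00406), and it and Ecm1 kept their calls with each Cre-negative or Dnmt1cKO library left out. The other 6 lost theirs. Among Cre-negative and Dnmt1cKO libraries, Zfp444 (0.048) lost it without any 1 but Cre-negative 6, and Ampd3 (0.048) without any but Cre-negative 2. Slc16a13 (0.0334) lost it without any of them but Cre-negative 3, Cre-negative 6 and Dnmt1cKO 2. Dnajb2 (0.0244) lost it without Cre-negative 2 or 3, Gins3 (0.0211) without Cre-negative 4 or 7, and P4ha3 (0.0249) without Cre-negative 1, 4 or 7, where the values in parentheses are adjusted p with all libraries and the highest without 1 was 0.111, for Ampd3 without Cre-negative 7.

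The call for Lars2, a mitochondrial leucyl-tRNA synthetase gene (log2 fold change 3.56 ± 0.71, adjusted p = 0.00726), rested on Dnmt1cKO 5, which held 52740 CPM. Without it the log2 fold change was 1.25 ± 0.46 (adjusted p = 0.228). The other Dnmt1cKO libraries held 692 to 5708 CPM and the Cre-negative ones 304 to 1808 CPM, with Dnmt1cKO 2 (692 CPM) and Dnmt1cKO 3 (1117 CPM) inside that range.

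Of 115 raised genes with annotated transcripts, 7 (A430078G23Rik, Cmah, Gm11127, Hist4h4, Psg23, Zfp575 and Zfp706) were linked in a chain of pairwise shared segments. Each segment had at least 200 bases at 85% identity or more (best matches of 214 to 296 bases). Pairs whose symbols began with the same 3 letters were not linked directly, and 1 segment common to all 7 was not shown. In 10 random sets of 115 tested genes at most 3 were linked. Whether reads of such segments spread over all transcripts that carry them was asked of the 26 tested carriers. Their median log2 fold change was -0.0443 (bootstrap 95% interval -0.53 to 0.55), which argues against an even spread over all 26. Carriers needed only 85% identity, and whether reads could be placed on copies that far apart was not tested. Spread among closer copies therefore stays open. Of the 26 carriers 6 were raised, with a median of 8.01, and 0 lower, and the other 20 had a median of -0.28 with 7 positive. A carrier had to match at least 3 of the 7 linked genes, which left out Hist4h4, the linked gene with the highest log2 fold change (10.49). This definition was settled after stricter ones had left 0 tested carriers, and no repeat annotation was used, so the segments are not identified. Expression that starts in such segments at some of the loci may explain the set and was not tested.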
